A study of Sus scrofa with 6 samples.

How the data were processed

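The data were 6 small RNA libraries of cultured pig immature Sertoli cells, 3 untreated and 3 given 250 µM AA2P, sequenced on an Illumina NovaSeq instrument in 1 lane per the labels' protocols. The authors deposited 1 table of TPM for all 6 libraries, with 1645 entries rounded to 2 decimals. Bowtie is named, with no version or role, per the submitters' processing notes. The genome build, the miRBase release, the number of mismatches allowed, the program that predicted the numbered entries and the handling of reads shared by copies are not given in the sources used here.

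The values were examined before any test. Each column sums to 999999.82 to 1000000.08 over all entries, known and predicted. Low values of all entries step by 1 shared amount per library, so no length term was seen and the deposited TPM behave as counted reads scaled to the same total in each library. The step gave the depths of 25.8 to 36.0 Mreads, and 3 reads, the floor that a count of 0 allows, correspond to 0.0834 to 0.116 TPM. Of the values of a library, 99.87 to 100.0% lay within 0.0051 TPM of a whole number of reads, where the rounding alone gives 26.3 to 36.7%. By a stricter rule 54.2 to 78.0% of the low values lay within 0.1 step of a whole number, under the limit of 95% set for treating the values as counts. Exact whole reads rounded to 2 decimals give the same 54.2 to 78.0%, so the limit could not be met at this rounding and the rule says nothing against whole reads. The values were tested in their deposited unit, as TPM on a log scale, and no count test was run. Floors and depths cover counting error only, since reads without molecular identifiers are not independent molecules. At 10 TPM a value rests on 258 to 360 reads. Within a group, the chi-square per degree of freedom between the implied reads of 2 libraries was 98.8 to 621, so no library was taken for a repeat of another. The file lists 3 sets of entries with identical values (miR-9, miR-9-1 and miR-9-2; miR-129a-5p and miR-129b; miR-199a-3p and miR-199b-3p), 7 entries in all, which were kept as deposited.

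Samples were grouped by their labels, and the comparison was AA2P against control. Entries with at least 1 TPM in at least 3 of the 6 libraries were tested (433: 264 known, 169 predicted), which held at least 99.8% of the TPM of each library. Values were transformed as log2(TPM + 1), so fold changes on this scale understate the change of low entries, while fold values in the text are ratios of mean TPM. limma 3.58.1 in R 4.3.3 fitted the 2 groups with a mean-variance trend and gave two-sided p-values, adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. No batch is named in the labels and no block was used: libraries that share a number deviated together with correlations of 0.29, 0.06 and 0.18, which are not all over 0.1. Pairing by number is not ruled out by this, and the number served as a block in an alternative.

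There were 20 miRNA lists, chosen before the data were examined like the tests, the filter and the rule for named miRNAs: the let-7, miR-15/16, miR-29, miR-30 and miR-181 families; the miR-17~92, miR-221 and miR-222, miR-23/27/24 and DLK1-DIO3 clusters; p53-induced, hypoxia-associated, NF-κB-induced and DNMT- or TET-targeting miRNAs; miRNAs of earlier pig Sertoli cell work and of gonadal somatic cells; and markers of germ cells, muscle and myoid cells, mesenchymal cells, blood and endothelium, and epithelium. Lists with at least 3 tested members (18) were compared with the other entries by camera with a preset correlation of 0.01 and adjusted together; camera with an estimated correlation and fry were run beside it. Members were matched by name and arm, where an entry without an arm stands for the main arm. In 1 point this departs from the rule as first written: after the names in the file were seen, and before any list was tested, miR-125a-3p, miR-212-5p and miR-1285-5p were not matched to the entry without an arm, which is another arm. miR-194-5p did not match miR-194a-5p or miR-194b-5p. Several lists share members (miR-107, miR-23a, miR-24-3p, miR-26a, miR-34c, miR-126-3p, miR-132, miR-145-5p, miR-155-5p, miR-199a-5p, miR-29), so they are not independent.

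Arm use was tested by limma on log2((5p TPM + 1)/(3p TPM + 1)) for hairpins whose arms each had a mean of at least 10 TPM. The share of the 10 most abundant miRNAs was compared by a two-sided exact permutation test. The miRNAs named were the 10 most abundant; the 12 largest rises and 12 largest falls among calls with a mean of at least 10 TPM; up to 4 members of each list with the highest mean TPM; miR-210 and the miR-29 family; and the 5 hairpins with the smallest p for arm use. miR-142-3p, miR-130a, miR-499-5p, miR-22-3p, let-7c and miR-375 fall outside this rule and were named to complete counts of called list members, after their values were seen.

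On data simulated from the means and depths of these libraries for the main comparison, with 200 miRNAs changed and 476 entries passing the filter, limma recovered 78.8% of 66 tested ones at 1.5-fold, 98.4% of 64 at 2-fold and 100% of 64 at 4-fold with 8 false calls, and with no change simulated it called 0 of 480. The simulated dispersion was 0.015 and gave a median residual SD of 0.173, against 0.181 in the real data. In the real data the median log2 fold change of all tested entries was 0.25, and the split of rises and falls depended on the scaling. False calls from such a shift were not assessed by the simulation, so the 8 are no error rate for these data. For the lists, 1 of 1 list changed 1.5-fold, the miR-30 family, was recovered. Entries were simulated independently of each other, whereas the correlation estimated for this list in the real data was 0.28. The simulation therefore says nothing about lists with correlated members. For arm use, 10 of 10 hairpins changed 2-fold were recovered. Smaller changes of the arm ratio were not simulated, although all those observed were under 2-fold, so this recovery says little about them.

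Alternatives covered the pseudocount, the filter, the scaling (trimmed mean, median of ratios, quantile, totals without the 10 most abundant), the variance model, the replicate number as a block, a 2-fold limit, and leaving out each library. Added after the data were seen were counting repeated entries once, known miRNAs only, and totals without miR-21-5p. Positions of known hairpins in Sscrofa11.1, of which 167 of 197 were matched by name, served only to find neighbours, and no coordinates are given because the build behind the deposited values is not given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.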

Results

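Small RNA was sequenced from immature Sertoli cells, the somatic cells that nurse germ cells in the seminiferous tubule, taken from pig testes at 80 to 90 days of gestation. The cells were seeded, cultured for 6 h in medium with 10% serum and then left untreated or given 250 µM L-ascorbic acid 2-phosphate (AA2P), a stable derivative of vitamin C. The length of the treatment was not given. The comparison of the 3 control libraries with the 3 AA2P libraries addressed which microRNAs (miRNAs) were abundant in these cells and which changed with AA2P. The labels do not say whether libraries of a group came from separate cultures or animals, so p-values measured only the spread between these samples, which may be technical. The deposited table listed 1645 entries in TPM (counts scaled to a common library total), of which 358 were known pig miRNAs and 1287 were predicted ones named by number. The smallest step between values put the depth at 25.8, 32.2 and 30.3 Mreads (counted reads, with M for mega) in the control libraries and at 26.9, 36.0 and 32.5 Mreads in the AA2P libraries, so that 1 TPM stood for 25.8 to 36.0 reads. Predicted entries took 0.378 to 0.408% of the TPM in the control libraries and 0.501 to 0.608% in the AA2P libraries. Levels are given as mean ± SD of the 3 libraries of a group.

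A single miRNA dominated the cells. miR-21-5p, a widely expressed miRNA, took 52.1% ± 0.876 of the TPM in controls and 41.1% ± 3.70 with AA2P (SD, n = 3 per group). It was followed by let-7i-5p (7.72% ± 0.269 and 9.16% ± 1.02), miR-30a-5p (6.35% ± 0.112 and 10.1% ± 0.645), let-7f-5p (3.36% ± 0.192 and 4.50% ± 0.592), let-7g (2.33% ± 0.180 and 3.15% ± 0.417) and miR-100 (2.25% ± 0.185 and 2.32% ± 0.220). The other members of the 10 most abundant were miR-10a-5p, miR-30d, let-7a and miR-92a, each at 1.17 to 1.97% of the TPM. Of these 10, miR-21-5p fell, while miR-30a-5p, let-7f-5p, let-7g and miR-30d rose (limma, adjusted p = 0.0254, 0.00238, 0.0382, 0.0393 and 0.0182). The miR-21-5p call ended in 10 of 22 alternatives, among them leaving out any 1 of the control libraries. The 2-fold limits, also among them, exclude a change of its size (log2 fold change -0.35). Under all other scalings but quantile normalization the fall was -0.54 to -0.64 and passed (limma, adjusted p = 0.0112 to 0.0223). Those scalings also lowered the median of all tested entries. The calls of let-7f-5p, let-7g and miR-30d ended under at least 3 of 5 other scalings. miR-92a, not called as deposited, passed as lower under all 5. Quantile normalization fixes the highest ranks to the same values in each library. It set the change of miR-21-5p and let-7f-5p to 0 and put let-7i-5p lower with AA2P. Together the 10 took 79.7% ± 0.673 of the TPM in controls and 76.7% ± 1.31 with AA2P, a difference of -2.97 percentage points. The groups did not overlap, and the two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. For the 20 most abundant the difference was -1.15 points, the groups overlapped and the two-sided exact permutation test gave p = 0.2.

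Many miRNAs differed between the AA2P and the control libraries. Among calls with a mean of at least 10 TPM, the steepest fall was that of miR-210, the miRNA best known for its induction by hypoxia, from 468.7 ± 42.4 to 78.1 ± 11.1 TPM, 6.00-fold lower. miR-146b and miR-146a-5p, which NF-κB induces and which restrain Toll-like receptor signalling, fell 3.12-fold and 2.36-fold, and the clustered miR-222 and miR-221-3p, which repress the cell cycle inhibitor CDKN1B, fell 2.69-fold and 2.17-fold. The steepest rise among these calls was that of miR-184, from 271.5 ± 29.4 to 1747 ± 354 TPM, 6.44-fold higher. miR-192 rose from 956 ± 55.1 to 2282 ± 230.3 TPM, with its relative miR-215 and its cluster partner miR-194a-5p, and miR-99a-5p, which represses MTOR, rose from 1529 ± 155 to 3283 ± 377 TPM.

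**Figure D1:**
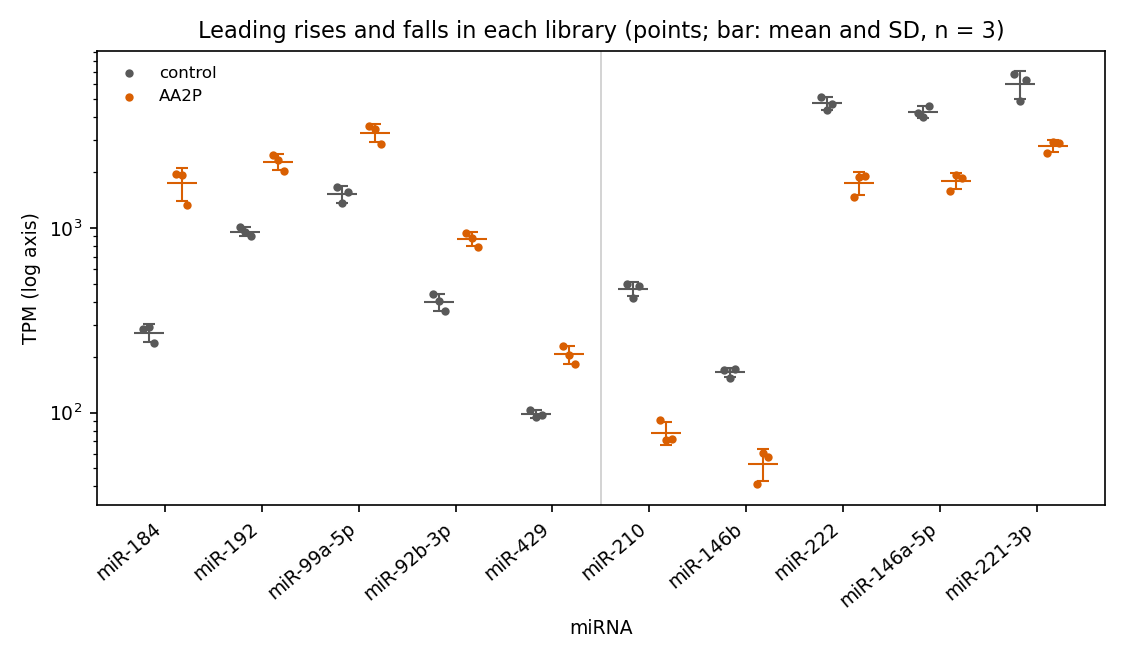
TPM (log axis) of 5 miRNAs that rose and 5 that fell in each of the 3 control and 3 AA2P libraries; points are libraries, and the bars give the mean and SD of a group. For each of the 10 miRNAs the 3 AA2P libraries lie apart from the 3 control libraries, as for miR-210 with means of 468.7 and 78.1 TPM.

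Other large rises among calls with a mean of at least 10 TPM were those of both arms of miR-92b (log2 fold change 1.30 for miR-92b-5p and 1.13 for miR-92b-3p), miR-32 (1.10), miR-181b (1.09), miR-429 (1.05) and the predicted entries Novel_1274 (1.32) and Novel_1130 (1.19). Smaller falls were those of miR-221-5p (-0.73), miR-152, which represses DNMT1 (-0.67), miR-574-5p (-0.64), miR-29b (-0.63), miR-155-5p (-0.61), miR-29a-3p (-0.42) and the predicted entry Novel_708 (-0.41). Of the 433 entries tested by limma on log2(TPM + 1), 107 passed an adjusted p of 0.05, 86 of them higher and 21 lower with AA2P, and 20 rises and 8 falls were of at least 2-fold on that scale. Known miRNAs made up 69 of the rises and 15 of the falls, and predicted entries 17 and 6. The adjusted p was 3.54e-04 for miR-210 (SE 0.128 on the log2 scale) and 9.40e-04 for miR-184 (SE 0.175). In the deposited TPM the 2 groups did not overlap for 215 entries (49.7%, where chance gives 10% for an entry taken alone). A shift shared by all entries of a library can separate many of them at once. The count was not repeated under other scalings, so its excess over 10% cannot be read as that many separate changes. The 12 largest rises and the 5 largest falls among calls with a mean of at least 10 TPM kept direction and call under all alternatives run in which they were tested.

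**Figure D2:**
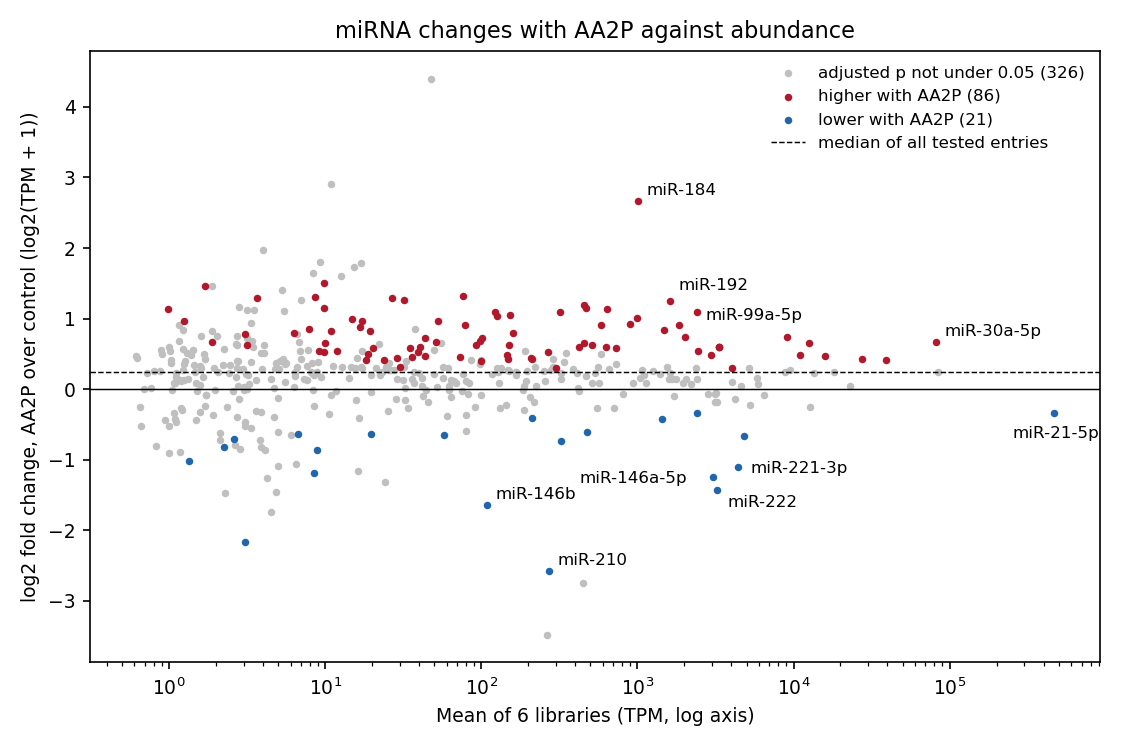
Log2 fold change of AA2P over control (on log2(TPM + 1)) against the mean TPM of the 6 libraries (log axis) for the 433 tested entries; red points were higher (86) and blue points lower (21) with AA2P at an adjusted p under 0.05, and grey points did not pass. The dashed line is the median of all tested entries, 0.25, and it lies above 0.

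The balance of rises and falls depended on the scaling. The median log2 fold change of all tested entries was 0.25 in the deposited TPM, and it was shifted by -0.25 with trimmed-mean scaling, by -0.26 with median-of-ratios scaling and by -0.26 with quantile normalization. The calls were then 47 higher and 49 lower, 48 higher and 51 lower, and 45 higher and 42 lower, and with the 10 most abundant miRNAs left out of the totals they were 55 and 36. Of the 107 calls, 49 (31 higher and 18 lower) held with the same direction under all 6 scalings. Without control replicate 3 the count of calls was 62 (54 higher and 8 lower), and without control replicate 2 it was 75 (62 and 13).

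Among miRNA families, the cluster of miR-221 and miR-222 moved most, with all 3 measured products lower (adjusted over the list alone, 3 as well). As a list it stood below the other miRNAs (camera with a preset correlation, adjusted p = 1.71e-04; adjusted p = 0.305 with an estimated correlation). In the miR-29 family, which represses collagens, miR-29a-3p fell from 1639 ± 159 to 1224 ± 23.2 TPM and miR-29b from 24.1 ± 1.26 to 15.4 ± 3.16 TPM, while miR-29c went from 4.43 to 3.35 TPM and did not pass; 2 members were lower over the list alone. The call of miR-29b ended in 8 of 22 alternatives and that of miR-29a-3p in 6. Neither ended under another scaling, but those scalings lowered the median of all tested entries and could hardly lessen a fall. The list stood lower (adjusted p = 0.00797; adjusted p = 0.305 with an estimated correlation). The miR-30 family stood higher (adjusted p = 0.0281; adjusted p = 0.433 with an estimated correlation), with 4 of 5 members higher and all 5 when adjusted over the list alone. miR-30a-5p rose 1.59-fold from 63458 ± 1124 TPM, miR-30c-5p 1.68-fold, miR-30e-5p 1.90-fold and miR-30d 1.39-fold. In the miR-181 family 2 of 4 members rose, miR-181a and miR-181b (2 over the list alone), but the list did not pass (adjusted p = 0.161). In the let-7 family 3 of 8 members rose, let-7c, let-7f-5p and let-7g (4 over the list alone), and the list did not pass (adjusted p = 0.186). The calls of let-7c, let-7f-5p and let-7g ended under trimmed-mean scaling, median-of-ratios scaling and totals without miR-21-5p. Whether reads shared by such near-identical members were split or counted more than once was not given, so single members are less certain than their family.

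Lists named for a pathway moved in both directions. Of 6 measured p53-induced miRNAs, 4 rose (5 over the list alone): miR-192, miR-215, miR-107 (505 ± 61.0 to 760.2 ± 54.3 TPM) and miR-34c (178 ± 8.01 to 242 ± 36.3 TPM). miR-34a went from 295 ± 33.8 to 384 ± 32.2 TPM and did not pass (adjusted p = 0.0577). The list stood higher (camera adjusted p = 0.0317; adjusted p = 0.433 with an estimated correlation). Its call ended under quantile normalization (0.0562), with known miRNAs only (0.0565) and without AA2P replicate 2 (0.0597). The call of miR-34c ended under all 5 other scalings, and that of miR-107 under 2 of them.

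Of 6 measured hypoxia-associated miRNAs, miR-210, miR-155-5p and miR-23a fell, miR-107 rose, and miR-24-3p and miR-26a did not pass (3 lower and 1 higher over the list alone). The list stood lower (adjusted p = 0.0145; adjusted p = 0.433 with an estimated correlation). Of 8 miRNAs known to target DNMT or TET transcripts, miR-29a-3p, miR-29b and miR-152 fell and miR-22-3p rose (3 lower and 1 higher over the list alone), and the list did not pass (adjusted p = 0.0675), although it did without control replicate 1 (0.0493) or AA2P replicate 1 (0.04997). With an estimated correlation its adjusted p was 0.433. The miR-152 call ended in 7 of 22 alternatives, among them quantile normalization and leaving out control replicate 2 or 3, and the miR-22-3p call under all 5 other scalings.

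Among the NF-κB-induced miRNAs, miR-146a-5p (4262 ± 309 to 1804 ± 185 TPM), miR-146b, miR-155-5p and miR-21-5p fell, and miR-9 rose from 2654 ± 79.2 to 4011 ± 346 TPM. The file lists miR-9 as 3 entries with identical values, so the list counted 3 higher and 4 lower of 8 entries (4 and 4 over the list alone), had a median log2 fold change of 0.12 and a mean of -0.17, and did not pass (adjusted p = 0.186; adjusted p = 0.433 with an estimated correlation). With repeated entries counted once it stood lower (adjusted p = 0.0110), and so it did with a mean of at least 10 TPM required (adjusted p = 0.0461). The rise of miR-9 did not pass with miR-21-5p left out of the totals. miR-142-3p, a miRNA of white blood cells, rose from 0.507 ± 0.0802 to 1.98 ± 0.627 TPM in the same libraries.

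**Figure D3:**
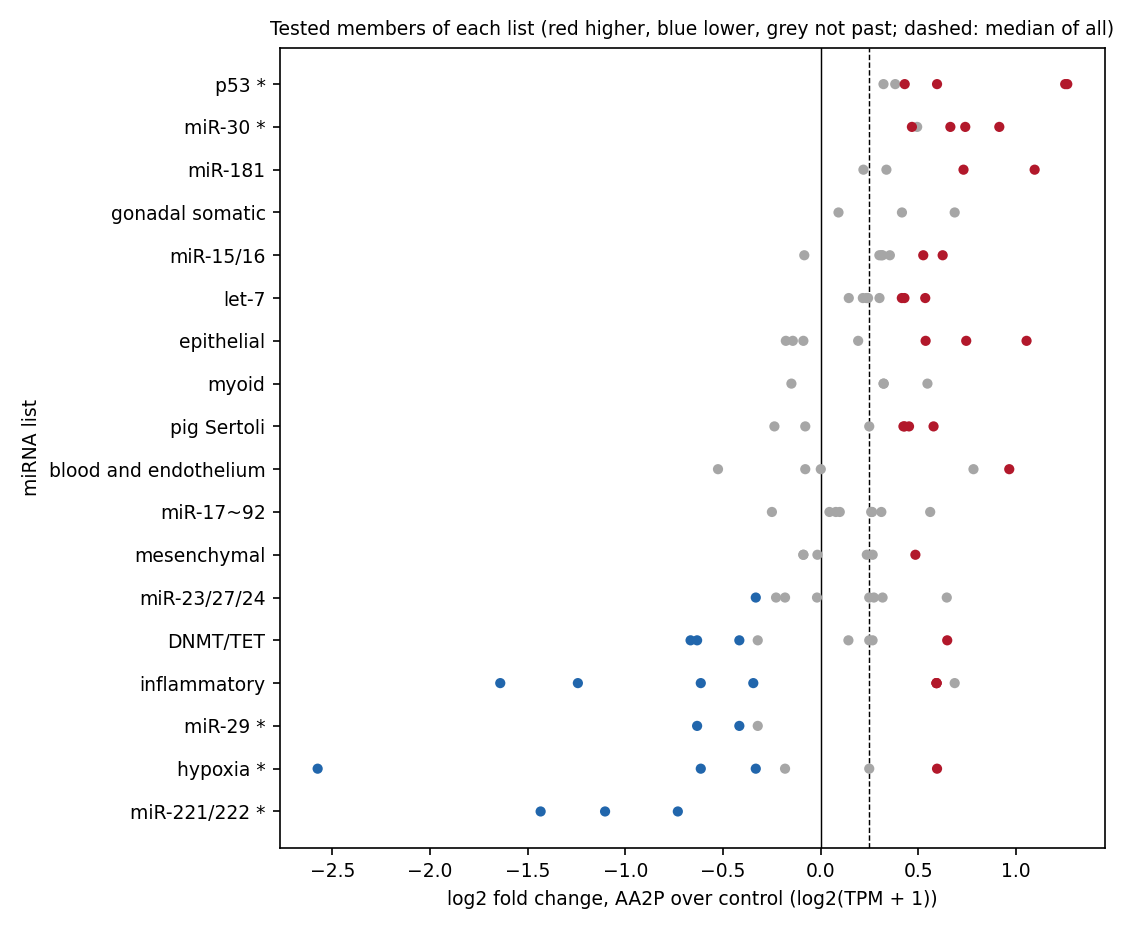
Log2 fold change of AA2P over control (on log2(TPM + 1)) of the tested members of the 18 lists with at least 3 of them; each point is a miRNA, red where it was higher, blue where it was lower and grey where it did not pass, and an asterisk marks the 5 lists called by camera with a preset correlation. The dashed line is the median of all tested entries (0.25). The 3 products of miR-221 and miR-222 lie between -1.43 and -0.73; none of the 5 lists was called with an estimated correlation.

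The lists of miR-17~92, miR-15/16, miR-23/27/24, earlier pig Sertoli cell work and gonadal somatic cells did not pass. None of 8 members of the miR-17~92 list was called (0 over the list alone; adjusted p = 0.830), with miR-20a-5p at 5770 ± 1123 and 6017 ± 314 TPM and miR-17-5p at 3906 ± 532 and 4156 ± 196 TPM. In the miR-15/16 family miR-503 and miR-424-5p rose among 7 members (2 over the list alone; adjusted p = 0.409). In the miR-23/27/24 clusters miR-23a fell from 2665 ± 80.7 to 2118 ± 105 TPM and the other 7 products did not pass (1 lower over the list alone; adjusted p = 0.409). Of 7 miRNAs from earlier work on cultured pig Sertoli cells, miR-34c, miR-362, miR-130a and miR-499-5p rose (4 over the list alone; adjusted p = 0.588). None of 3 gonadal miRNAs passed over all entries, and 2 were higher over the list alone (adjusted p of the list 0.526): miR-140-3p stood at 1106 ± 61.5 and 1178 ± 69.9 TPM, and quantile normalization put it lower with AA2P. The calls of miR-424-5p, miR-362 and miR-130a ended under all 5 other scalings, that of miR-503 under 4 and that of miR-499-5p under 3. Some falls gained a call under these scalings, which lowered the median of all tested entries. Among them, miR-92a passed as lower under all 5, and miR-27a and miR-24-3p under 4.

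Lists for other cell types did not pass either. Of 7 epithelial miRNAs, miR-200b (1496 ± 41.9 to 2519 ± 297 TPM) and miR-429, which repress ZEB1 and ZEB2, and miR-375 rose (3 over the list alone; adjusted p = 0.712), while miR-182 stood at 6662 ± 413 and 6310 ± 1034 TPM and miR-183 at 4413 ± 165 and 4016 ± 515 TPM. Of 6 mesenchymal miRNAs, miR-10b rose (1 over the list alone; adjusted p = 0.913). None of 4 muscle and myoid miRNAs passed (0 over the list alone; adjusted p = 0.913), with miR-143-3p at 34.6 ± 10.7 and 30.8 ± 8.22 TPM. Of 5 blood and endothelial miRNAs, miR-142-3p rose (1 over the list alone; adjusted p = 0.696), and miR-126-3p stood at 101 ± 6.50 and 96.4 ± 12.2 TPM. The germ cell and DLK1-DIO3 lists had 1 tested member each, miR-34c, which rose, and miR-381-3p at 1.15 ± 0.235 and 1.47 ± 0.871 TPM, and were not tested as lists. The calls of miR-10b and miR-375 ended under all 5 other scalings, and that of miR-142-3p under trimmed-mean scaling and totals without miR-21-5p. Under these scalings, which lowered the median, miR-183 passed as lower in 4 and miR-126-3p in 3. miR-182 passed as lower with totals without miR-21-5p only. Over the 18 lists, camera called 5 with a preset correlation and 0 with an estimated one, and fry, which asks only whether members move one way on balance, called 9. For the miR-17~92, miR-23/27/24, mesenchymal, blood and NF-κB lists the median or mean log2 fold change was above 0 while camera, which sets a list against the other miRNAs, gave the direction down.

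The use of the arms of a hairpin was compared within libraries, where scaling cancels. None of 39 hairpins with both arms measured was called by limma (smallest adjusted p = 0.282), and 4 had an unadjusted p under 0.05: miR-500, miR-374b, miR-28 and miR-7134. The log2 ratio of the 5p to the 3p arm of miR-500 went from -0.87 ± 0.182 to -0.42 ± 0.0209, and that of miR-140, the hairpin next in order of p, from -3.69 ± 0.229 to -3.36 ± 0.117. Without control replicate 2 there were 3 calls, for miR-129a, miR-221 and miR-365.

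The correlations of libraries within and between groups overlapped in range. Over the tested entries Pearson's r of log2(TPM + 1) was 0.962 to 0.985 within groups and 0.958 to 0.978 between them, with means of 0.974 and 0.967. The first principal component held 36.5% of the variance and placed the control libraries at -8.86 to -5.62 and the AA2P libraries at 1.89 to 12.3, and the second held 25.5%.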

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

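The weighing of blood cells, of hypoxia-inducible factor and of the predicted entries was chosen only after the results were seen. So were the limits of 5, 20 and 100 TPM used here for untested and predicted entries, but not the limit of 100 TPM used to weigh depth. The other tests were set after a first look at the fold changes and before their own values were seen. The limit for printing single entries was raised to 100 TPM for predicted entries to shorten the list.

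A signal appeared in at least 1 AA2P library in 4 entries that were too rarely detected to be tested and that lay under 1 TPM in all 3 control libraries. miR-223, a miRNA of myeloid cells, reached 5.40 TPM in AA2P replicate 1 and 0.06 TPM in the next AA2P library, with at most 0.04 TPM in controls. Of the predicted entries, Novel_265 reached 1216 TPM in AA2P replicate 2 alone and 1 further entry 141 TPM in AA2P replicate 1 alone, both listed at 0 in the other AA2P libraries, and Novel_316 stood at 145.98 and 140.15 TPM in AA2P libraries; all were listed at 0 in controls. At a limit of 5 TPM there were 34 such entries, and 22 in the opposite direction.

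High values stood beside listed zeros among predicted entries. Of 60 predicted entries that reached 20 TPM in some library, 32 were listed at 0 in another, against 0 of 199 known miRNAs. None of these 32 was at 0 in all libraries of one group and above 0 in all of the other (0 entries), which argues against an on or off response to AA2P. The values above 0 of these entries included 0 (of 69) under 1 TPM, a share of 0%. By selection at least 1 value of each entry was at least 20 TPM, so only the remaining values could have been that low. Such values would arise if a predicted entry was counted only in the libraries in which it was predicted. That remains a hypothesis, since the prediction step is not described in the sources used here. Of the 23 called predicted entries, 2 had a listed 0, and so had 0 of the 84 called known miRNAs.

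More miRNAs rose than fell (86 against 21). Deeper AA2P libraries would act near the floor, but among calls with a mean of at least 100 TPM 78.2% were rises, which argues against depth. With miR-21-5p left out of the totals 47.6% of the calls were rises, but this lowers all other entries by nearly the same step and took the median log2 fold change from 0.25 to -0.01, so the even split follows from the step. Per-million scaling, which lifts the other miRNAs where the share of miR-21-5p falls, and a biological excess of rises cannot be told apart in relative values, and the balance of rises and falls stays open.

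The falls of miR-210, miR-146a-5p, miR-146b, miR-221-3p and miR-222 stood apart from that shift. Over 5 other scalings the smallest of these falls was -1.12 (log2). Those scalings shifted the median log2 fold change by -0.26 to -0.18. They could thus hardly lessen a fall, and the comparison cannot weigh per-million scaling. The falls do run against the median of 0.25 in the deposited TPM. A loss of blood cells would remove their miR-142 as well, but the higher arm of miR-142 in controls came to 0.0206% of the miR-146a-5p lost (2458 TPM), and miR-142-3p rose. A candidate explanation for miR-210 is lower activity of hypoxia-inducible factor, whose hydroxylases use ascorbate. The mean log2 fold change of the other 5 members of the hypoxia list, less that of all other tested entries, was -0.28. Camera gave an unadjusted p of 0.0594 for these members. Their own values were mixed: miR-155-5p (-0.61), miR-23a (-0.33) and miR-24-3p (-0.18) lay below 0, miR-26a (0.25) and miR-107 (0.60) above. With so few members the explanation cannot be told apart from an effect on miR-210 alone.

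Of the 10 ways to split the 6 libraries into 3 and 3, the real one gave 107 called miRNAs, 5 called lists and 0 called hairpins, and the highest of the others gave 4, 1 and 2. As many calls came in 1, 1 and 10 of the 10 splits, the real one included, and 10 splits are too few for a share under 0.05.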

How the results depend on the processing

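Totals without miR-21-5p, repeated entries counted once, known miRNAs only and the settings for library correlations were chosen after the data were seen; the others were planned. Counts of calls (main 107, with 86 higher and 21 lower) stayed within 1.5 times under other pseudocounts and variance models, a mean of at least 10 TPM, repeated entries counted once and known miRNAs only. With no filter there were 57 (48 and 9), where 1645 entries were adjusted together; with a 2-fold limit on log2(TPM + 1) 28 (20 and 8), or 33 (24 and 9) at an unadjusted p under 0.05. The split moved to 47 higher and 49 lower with trimmed-mean scaling, 48 and 51 with median-of-ratios scaling, 45 and 42 with quantile normalization, 55 and 36 without the 10 most abundant, and 39 and 43 without miR-21-5p. Leaving out each library in turn, with 1 fewer sample in a group, gave 62 to 98 calls (54 to 78 higher, 8 to 20 lower), 4 to 6 lists, 0 to 3 hairpins and a difference in the share of the 10 most abundant of -3.70 to -2.44 points; it was -1.15 for the 20 most abundant, where the cause was not tested. With the replicate number as a block there were 63 calls (52 and 11) with 2 residual degrees of freedom. Of these, 62 were among the 107, and 5 lists and 0 hairpins were called. Same-number deviations correlated at 0.29, 0.06 and 0.18, and those of different numbers across the groups at -0.26 to 0.11. Control replicate 2 correlated best with AA2P replicate 3 and every other library with its own number. The numbers were not taken to pair the libraries, but pairing is not ruled out. Lists called by camera fell from 5 to 0 with an estimated correlation.

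Of 79 named miRNAs 43 were called, and 17 of these kept direction and call everywhere. The 2-fold limits alone took the call from 26, so these limits set the count of 17. The call was lost by 16 without control replicate 3, 14 without control replicate 2 and 14 with no filter. It was lost by 12 without miR-21-5p in the totals, 11 with the block and at most 10 in any other. Quantile normalization put let-7i-5p at -0.21 and miR-140-3p at -0.33, both called there and on the other side of 0 as deposited. It fixes the highest ranks to the same values in each library, which sets let-7i-5p by construction. The deposited value of miR-140-3p (0.09) lay under the median of all tested entries (0.25), which all other scalings lowered. Under the remaining scalings it stood at -0.20 to -0.10 and was not called. Why it passed under quantile normalization only was not tested. A further 78 sign changes concerned values called on neither side. The 2 planned count tests were not run, since the rule set for them could not be met by values rounded to 2 decimals, so how far they would differ is not known. Depth of 25.8 to 36.0 Mreads limits entries near 1 TPM, which rest on 25.8 to 36.0 reads.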

Other observations

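The tests of neighbouring miRNAs and of the correlation of the arms were chosen only after fold changes had been seen.

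Epithelial miRNAs summed to 13162 ± 293 TPM in controls and 13607 ± 1779 TPM with AA2P, mostly miR-182 and miR-183, with miR-205 at 0.157 ± 0.134 TPM in controls. Mesenchymal miRNAs summed to 25980 ± 1130 TPM in controls and 32760 ± 3962 TPM with AA2P, mostly miR-10a-5p (16649 ± 513 TPM in controls) and miR-10b (9191 ± 720 TPM). The mesenchymal miRNAs other than these and miR-196b-5p were each under 2 TPM in controls: miR-199a-5p stood at 0.133 ± 0.123 TPM, miR-214-3p at 0.0233 ± 0.0208 TPM, miR-199b-5p at 1.98 ± 0.280 TPM and miR-199a-3p, whose values are identical to those of miR-199b-3p, at 1.81 ± 0.421 TPM. The 11 measured products of the imprinted DLK1-DIO3 cluster summed to 1.71 ± 0.229 TPM in controls and 2.00 ± 0.996 TPM with AA2P. miR-202-5p, a gonadal miRNA, stood at 0.657 ± 0.316 and 0.517 ± 0.142 TPM.

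Fold changes of neighbouring miRNAs were closer to each other than shuffled ones. In the miR-450 and miR-542 group, named after its values were seen, miR-450b-5p (log2 fold change 0.84), miR-450c-5p (1.00), miR-450c-3p (0.99), miR-450a (0.91) and miR-542-3p (0.92) rose, while miR-450b-3p (0.30) and miR-542-5p (0.75) did not pass. The call of miR-542-3p ended under quantile normalization and without miR-21-5p in the totals, and that of miR-450c-3p under quantile normalization. miR-192 and miR-194a-5p rose (1.25 and 1.14), and so did miR-215 (1.26), whose neighbour miR-194b-5p did not pass (1.11). Some of the pairs tested below lay on both sides of 0, with neither member called in the deposited TPM. Examples were miR-92a (-0.25) with miR-19a (0.56) and miR-24-3p (-0.18) with miR-23b (0.32). miR-24-3p was also paired with miR-23a (-0.33) and miR-27a (-0.23), which lay on its own side of 0. Of the 5 other scalings, miR-92a passed as lower under all 5 and miR-24-3p under 4. The mean absolute difference in log2 fold change was 0.227 over 63 pairs of miRNAs whose hairpins lie within 10 kb of each other, against 0.573 for shuffled fold changes (one-sided permutation p = 1e-05, the smallest that 100000 resamples give), and 0.242 over the 50 pairs with different miRNA numbers (p = 3e-05). A first run that kept 3 arms named for a numbered copy, which pair with their own hairpin, gave 0.241 over 71 pairs. Fold changes were shuffled over all matched hairpins, also those without a neighbour, so the shuffled mean does not describe paired hairpins alone. Pairs share members and are not independent, so the p-values are approximate. A candidate explanation is a shared change of the primary transcript, which was not measured.

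The arms of a hairpin also changed together: over 39 hairpins the log2 fold changes of the 5p and 3p arms correlated with Spearman's rho = 0.741 and Pearson's r = 0.887 (two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples give). The correlation is across hairpins, which are not independent replicates, and a scaling that moves all entries alike leaves it nearly unchanged. A shared change of the precursor would give such a correlation, but the correlation does not exclude changes of arm choice. No hairpin passed the test of the arm ratio, for which changes under 2-fold were not simulated.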
